A study of Homo sapiens with 4 samples.

How the data were processed

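Chromatin accessibility was measured by ATAC-seq in NK92 cells, a human natural killer cell line that grows in the presence of interleukin-2. ATAC-seq uses the Tn5 transposase to insert sequencing adapters into open chromatin, so that reads pile up where nucleosomes leave the DNA exposed. The 4 libraries comprised 2 from untreated cells and 2 from cells given 1000 nM SAHA for 24 hours, all given as 12 passages in the labels. SAHA (vorinostat) is a hydroxamate inhibitor of histone deacetylases. The series design calls the libraries biological replicates and does not say how the cultures were separated, so the spread between them may in part be technical.

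The deposited data were 4 peak lists in the 10-column layout of a MACS narrowPeak file, with 1 list per library. The submitters' processing notes name the hg19 genome build, Bowtie2 2.3.5.1, Picard 2.27.4, MACS2 2.2.7.1 and deepTools 3.5.1, without settings or order. Any shift of reads for the Tn5 insertion site, removal of duplicate reads or use of an exclusion list is not given in the sources used here. Peak ends reached base 249219674 of chromosome 1, beyond the last gene of that chromosome in a GRCh38 gene table, so the coordinates were treated as hg19 throughout. The peaks in each deposited list carried a score, which was the whole part of 10 times the −log10 q-value in 99.986% to 100% of the peaks of a list. The deposited fold enrichment of a peak is its own value over the background of the same library, and the deposited −log10 p-value and −log10 q-value belong to the same summit. No deposited peak had a −log10 q-value below 1.30, which corresponds to a q-value threshold of 0.05. No peak was narrower than 100 bp, and no peaks overlapped within a list. Peak names were numbered up to 36633 and 33571 in control replicates 1 and 2 and up to 32390 and 29215 in SAHA replicates 1 and 2, and 530, 516, 489 and 416 of these numbers were absent from the lists. The filter behind this is not given in the sources used here. The peak names also carry library codes that the labels do not explain, and the group of each list was taken from the sample labels, not from these codes.

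The read depth of the libraries is not given in the sources used here. The deposited fold and −log10 p-value of each peak were therefore solved together for the number of reads at the summit and the background expected there, taking fold as (reads + 1)/(background + 1) and p as the upper tail of a Poisson distribution. A whole number of reads matched the deposited p-value within 0.005 for 100% of the peaks in every list. The background floor of a list, taken as the 1st percentile of these background values, rises with the depth of its library if the read extension was the same. It was 0.250 and 0.295 reads in control replicates 1 and 2 and 0.244 and 0.249 reads in SAHA replicates 1 and 2. Summits held a median of 16 to 19 reads, and the weakest peaks rested on 3 or 4 reads. Reads at a summit are not independent molecules if duplicates remained, so the intervals given cover counting error only.

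Peaks on chromosomes 1 to 22 and X were used, which left out between 58 and 70 peaks per list. All lists were merged where peaks shared at least 1 bp. A merged region was assigned to a library when that library had a peak in it. A region was called gained when both SAHA lists and neither control list had it, lost when both control lists and neither SAHA list had it, and shared when all 4 lists had it. Regions present in both libraries of a group and in 1 library of the other were called partly lost or partly gained. Regions in both libraries of at least 1 group formed the consensus set. Because each list was called separately, peak heights were not tested between lists, and absence of a peak means that no call was made, not that the chromatin was closed. Strength was the lower of the 2 percentile ranks of a region's score within its own lists. With 2 libraries against 2, an exact two-sided permutation test across libraries cannot give a p below 0.3333, so no such test was made for values per library. The 2 crossed splits, which set 1 control and 1 SAHA library against the others, served as a rough measure of what replicate differences alone give, in counts and, chosen after the data were examined, in spacing. The libraries allow only 3 such splits, so the SAHA and control split being the largest has the same limit of 0.3333. Lists of equal length were made by taking the 28741 strongest peaks of each library, the size of the shortest list. The overlap of 2 lists was the Jaccard index of covered bases, computed in Python in place of the planned bedtools. Distances were taken between the centres of regions. Proportions have exact Clopper-Pearson 95% intervals. Medians of gained and lost regions (distances on a log10 scale) were compared by two-sided permutation of the region labels (100000 draws, smallest possible p 1e-05), and ratios of medians have 95% bootstrap intervals from 2000 resamples. These tests, and the Fisher's exact tests, take regions as units and describe these lists, not the variation between cultures. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. On simulated lists with known classes, all 1801 gained, 3583 lost and 25181 shared regions were recovered, and all 20000 simulated summit read counts were recovered from rounded values. The simulated lists were copies of peaks of 1 list with slightly trimmed ends and no missed calls. Their recovery checks the computation only and gives no error rate for the gained and lost calls. With no difference simulated, the permutation test of medians gave p below 0.05 in 7 of 100 sets. These sets were independent normal values, without clustering along the genome or differences between libraries. They check the computation only and give no error rate for the comparisons of regions.

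The definitions of gained, lost and shared regions, the alternatives for them and the rule for naming regions were set before the data were examined. The regions named are the 15 gained and the 15 lost regions of highest strength. The rule also asked for the nearest gene of each region and for genes of fixed lists, which could not be applied. The spacing, chromosome, width and order comparisons were chosen after the lists had been examined. Neighbour windows of 100, 500 and 2000 kb and rank gaps of 0, 10, 20 and 30 points were looked at before 1 of each was chosen. Strong calls, above the 50 percentile of both lists, had been set beforehand, and strengths above the 25 and 75 percentiles were looked at in addition. A search for clusters of gained or lost regions in windows of 1 and 5 Mb was also made. The alternatives were a stricter overlap, merging of peaks within 200 bp, the peaks above the 50 percentile of each list, lists of equal length, strong calls only, all chromosomes and leaving out each library. Gene and promoter assignment, the gene lists, markers of other cell types and transcription factor motifs had also been planned. They were not analysed here, because no hg19 gene annotation or sequence was used and coordinates were not converted from another build. Regions are therefore identified by position alone.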

Results

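Accessible chromatin was mapped in 4 ATAC-seq libraries of NK92 natural killer cells, 2 from untreated cells and 2 from cells exposed to the histone deacetylase inhibitor SAHA at 1000 nM for 24 hours. The question was how SAHA alters the set of open regions across the genome. The deposited lists held 36033 and 32995 peaks for control replicates 1 and 2, and 31831 and 28741 peaks for SAHA replicates 1 and 2, on chromosomes 1 to 22 and X. Positions are hg19 coordinates counted from 1, and the genes or gene parts at these positions were not assigned.

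Fewer open regions were called after SAHA, and they covered less of the genome. Control libraries had 34514 ± 2148 peaks (SD, n = 2) and SAHA libraries 30286 ± 2185 (SD, n = 2), a mean lower by 12.3% with no overlap between the groups. Peaks covered 7.81 ± 0.39 Mb in control and 6.72 ± 0.40 Mb in SAHA libraries (SD, n = 2 each), lower by 14.0%. The median peak was 184.5 ± 3.5 bp wide in control and 178 ± 2.8 bp in SAHA libraries (SD, n = 2 each). The background floor, which follows read depth, was 0.272 ± 0.032 reads in control and 0.247 ± 0.003 reads in SAHA libraries. An exact permutation test of 2 libraries against 2 cannot go below p = 0.3333, so these differences are given as values only. The gap between the group means was wider than the SD within either group for peaks, covered bases and width, and narrower than the control SD for the background floor.

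The open regions of treated and untreated cells were largely the same. Libraries of the same group shared more of their covered bases than libraries of different groups. The Jaccard index was 0.682 for the control pair and 0.659 for the SAHA pair, against 0.613 to 0.631 for the 4 pairs that joined a control and a SAHA library. In lists of equal length the index was 0.712 and 0.675 within groups against 0.645 to 0.653 between groups. The difference between the within-group and between-group means was 0.0473, and 0.0288 without control replicate 1. Merging the lists gave 44067 regions, of which 21816 were present in all 4 libraries. These shared regions made up 71.6% (95% interval 71.1 to 72.1%) of the 30470 consensus regions, those present in both libraries of at least 1 group.

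Shared regions were also narrower after SAHA. The peaks within them had a median width of 244 and 239 bp in control replicates 1 and 2, and of 221 and 215 bp in SAHA replicates 1 and 2. In 6925 of the shared regions (31.7%) both SAHA libraries covered fewer bases than both control libraries, and in 2640 (12.1%) both covered more. In the 2 crossed splits of the same libraries the corresponding shares lay between 10.7% and 16.6%. The width of a called peak depends on depth and on the calling threshold as well as on the extent of open chromatin.

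Regions that were lost after SAHA outnumbered those that were gained. A total of 2615 regions were lost, 8.58% (95% interval 8.27 to 8.90%) of the consensus set, and 744 were gained, 2.44% (2.271 to 2.621%). The partial changes ran the same way, with 3608 partly lost and 1687 partly gained regions. The SAHA and control split gave 3359 gained and lost regions together, compared with 1547 when the 2 replicates numbered 1 were set against the 2 numbered 2, and 1338 for the other crossed split. The number of lost regions lay above every 2-library pattern of the crossed splits, which held 431 to 1116 regions, whereas the number of gained regions lay within that range.

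Lost and gained regions were closer in number in lists of equal length, a trimming that by itself draws the 2 counts together. When each library was represented by its 28741 strongest peaks, 1390 regions were lost and 1173 gained, a ratio of 1.19 in place of 3.51. In these lists of equal length the 4 crossed patterns held 572 to 589 regions (mean 578.5, SD 7.42). Lost regions were 2.40 times and gained regions 2.03 times as numerous as the mean of these patterns. Trimming took weak peaks out of the longer lists, so a region called gained or lost here can have a peak of the other group in the full lists. Equal lengths also draw the crossed patterns together, from 431 to 1116 in the full lists, so their small SD does not measure replicate differences. In the full lists the ratio was 2.49 without SAHA replicate 1 and 1.12 (4055 lost and 3606 gained) without SAHA replicate 2, settings in which 1 list is enough for a gained region and 2 are still needed for a lost one.

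**Figure D1:**
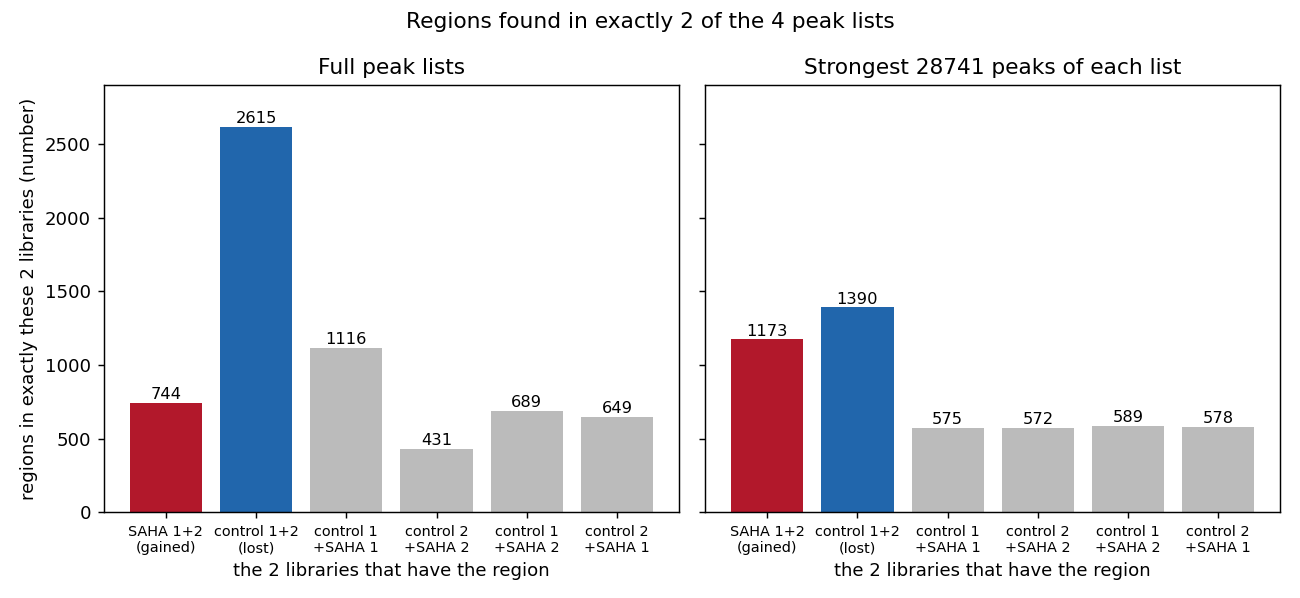
Number of merged regions present in exactly 2 of the 4 peak lists (vertical axis), for the full lists (left) and the 28741 strongest peaks of each library (right). Coloured bars are the 2 libraries of 1 group, 744 gained and 2615 lost on the left and 1173 and 1390 on the right, and grey bars are pairs that join a control and a SAHA library.

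Gained and lost regions were mostly weak peaks. They were narrow, with a median width of 142 bp for gained and 163 bp for lost regions against 282 bp for shared regions. Gained regions had a median of 8 and 9 summit reads in SAHA replicates 1 and 2, and lost regions 11 in each control replicate. Shared regions had medians of 26 reads in both control libraries and of 21 and 20 reads in the SAHA libraries. The median strength of gained regions was the 13.99 percentile of their lists and that of lost regions the 15.04 percentile. Above the 50 percentile of both lists, 31 regions were gained and 71 lost, 102 in all, against 32 and 22 in the crossed splits. The crossed patterns taken singly held 6 to 26, so the gained count lay only a little above them. Above the 75 percentile only 4 regions were gained or lost, against 1 and 2.

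The strongest gained region lay on chromosome 3 from 15309580 to 15309698. Its fold over background, the value of the authors' peak caller, was 17.2 ± 3.6 with 32.5 ± 10.6 summit reads (SD, n = 2 SAHA libraries), with no peak in either control library. The next was on chromosome 11 from 32830870 to 32830994, with a fold of 15.6 ± 1.3 and 19.5 ± 2.1 reads. A region on chromosome 6 from 31707676 to 31707789 followed, with a fold of 15.2 ± 1.1 and 18 ± 1.4 reads, and lay 366 kb from the nearest shared region. The next regions were on chromosome 9 from 19174324 to 19174482, with a fold of 14.0 ± 1.3, and on chromosome 10 from 98402830 to 98402980, with a fold of 12.4 ± 0.16. The other 10 of the 15 strongest gained regions had folds of 9.73 to 14.6. They began at 75867797 on chromosome 2, 203309296 on chromosome 1, 91315291 on chromosome 5, and 28670852 and 101471029 on chromosome 10. The rest began at 134291214 on chromosome 7, 73899303 and 109735255 on chromosome 8, 132869490 on chromosome 9 and 173314777 on chromosome 5. The last of these lay 0.396 kb from the nearest shared region and was no longer called gained when peaks within 200 bp were merged.

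The strongest lost region lay on chromosome 17 from 44271363 to 44271480. Its fold over background was 28.1 ± 1.8 with 41.5 ± 3.5 summit reads (SD, n = 2 control libraries), above the 94.0 percentile of both control lists, and neither SAHA list had a peak there. A region on chromosome 2 from 239279518 to 239279668 had a fold of 19.3 ± 0.75 and 27.5 ± 0.71 reads. On chromosome 16 from 60990 to 61110 the fold was 17.3 ± 0.67. Lost regions on chromosome 9 from 115479983 to 115480134 and on chromosome 8 from 66866761 to 66866974 had folds of 13.6 ± 0.72 and 12.0 ± 2.0. These 2 regions lay 0.424 and 1.27 kb from the nearest shared region, and the one on chromosome 9 was no longer called lost when peaks within 200 bp were merged. The other 10 of the 15 strongest lost regions had folds of 7.90 to 15.9. They began at 172349990 on chromosome 1, 39050198 on chromosome 19, 94437026 on chromosome 14, 125744542 on chromosome 11 and 24253494 on chromosome 13. The remaining 5 began at 37678432 on chromosome 22, 66695349 on chromosome 15, 57724980 on chromosome 20, 242557 on chromosome 9 and 13432217 on chromosome 6.

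Gained and lost regions differed in where they lay relative to the shared open regions. Gained regions had a median distance of 30.5 kb to the nearest shared region (quartiles 7.80 and 96.9 kb). Lost regions were close to shared ones, with a median of 5.92 kb (quartiles 0.880 and 23.3 kb). The medians differed 5.15-fold (95% bootstrap interval 4.26 to 6.73, permutation p = 1e-05, the smallest the test can give). Of the lost regions, 945 (36.1%) lay within 2 kb of a shared region, compared with 86 (11.6%) of the gained regions (two-sided Fisher's exact test, odds ratio 0.231, p = 1.57e-42). This p takes regions as units and does not cover differences between libraries. At 2 kb or more lay 658 of 744 gained and 1670 of 2615 lost regions. For both replicates numbered 1 it was 942 of 1116 regions, and for both numbered 2 it was 331 of 431, a contrast that was not tested. The 2885 regions of the crossed pairs had a median distance of 18.7 kb, from 11.9 kb for both replicates numbered 2 to 27.1 kb for both numbered 1. These last medians differed 2.28-fold (95% bootstrap interval 1.83 to 2.69) with no contrast of treatment, less than gained against lost regions. Regions found in a single library had medians of 16.9 and 8.51 kb in control replicates 1 and 2 and of 37.4 and 18.8 kb in SAHA replicates 1 and 2, so distances also differed between libraries of a group. The gained median exceeded the lost median on 23 of 23 chromosomes, where regions of both replicates numbered 1 exceeded those of both numbered 2 on 19, and in lists of equal length the medians were 29.4 and 6.05 kb. The ratio of gained to lost medians was 1.96 without control replicate 2 and 3.14 without SAHA replicate 1. It was 2.12 among peaks above the 50 percentile of each list and 2.94 among strong calls. Thus 2 of these alternatives lay below the 2.28 of the crossed pairs, a value of the full lists with all libraries. The ratio of the crossed pairs was not computed under these alternatives.

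**Figure D2:**
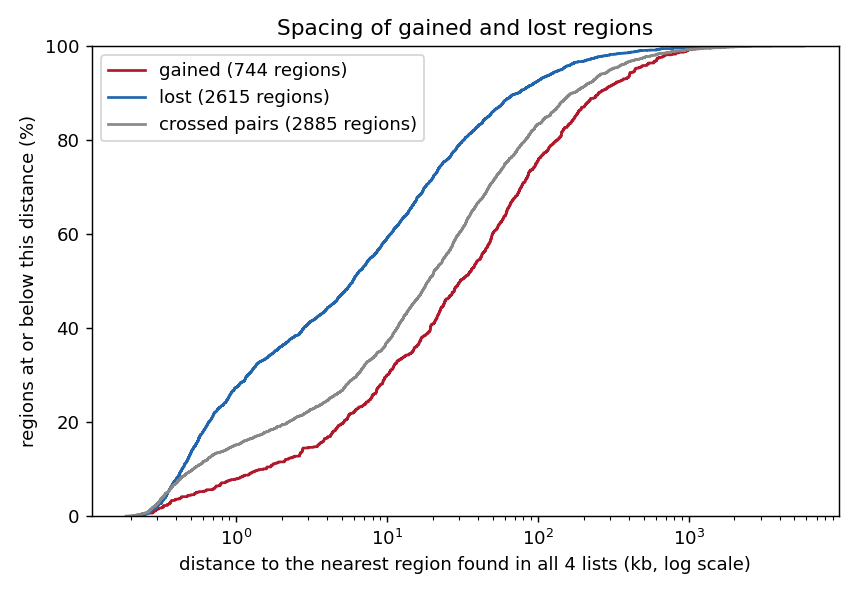
Cumulative share of regions (vertical axis, %) by distance to the nearest region found in all 4 lists (horizontal axis, kb, log scale), for gained, lost and crossed-pair regions. The gained curve lies to the right, with a median of 30.5 kb, and the lost curve to the left, with a median of 5.92 kb.

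Gained regions also had fewer open regions in their wider surroundings. Within 500 kb of a gained region there was a median of 21 other merged regions, compared with 29 around lost and 30 around shared regions (permutation p = 1e-05 for gained against lost). The gained minus lost difference of these medians was -8, and was -5 without control replicate 1, -3 without control replicate 2, -5 without SAHA replicate 1 and -2.5 among peaks above the 50 percentile of each list. These medians were not computed for the crossed splits, so what replicate differences alone would give is not known. The permutation p takes regions as units and does not cover differences between libraries. No window of 1 or 5 Mb held more gained or lost regions than its consensus regions would give after Benjamini-Hochberg adjustment of hypergeometric tests. At an unadjusted 0.05, 54 of 1702 windows of 1 Mb passed for gained and 50 for lost regions, and 21 and 28 of 558 windows of 5 Mb.

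The gained share of gained and lost regions was compared between chromosomes. It was 22.1% over all chromosomes and 12.6% (95% interval 7.51 to 19.4%) on chromosome 15. Chromosome 4 had 42 gained and 98 lost regions (95% interval of the gained share 22.6 to 38.3%). The variation over 23 chromosomes did not pass the threshold (permutation p = 0.0848), and no single chromosome did after Benjamini-Hochberg adjustment of Fisher's exact tests, with 2 below an unadjusted 0.05. In lists of equal length the variation did pass (permutation p = 0.0289), and chromosome 15 had a gained share of 30.4% against 45.8% overall (adjusted p = 0.036, Fisher's exact test). With 1 library left out, the permutation p of the full lists was 0.00653 without control replicate 1, 0.0298 without SAHA replicate 1, 1e-05, the smallest it can give, without SAHA replicate 2 and 0.613 without control replicate 2.

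**Figure D3:**
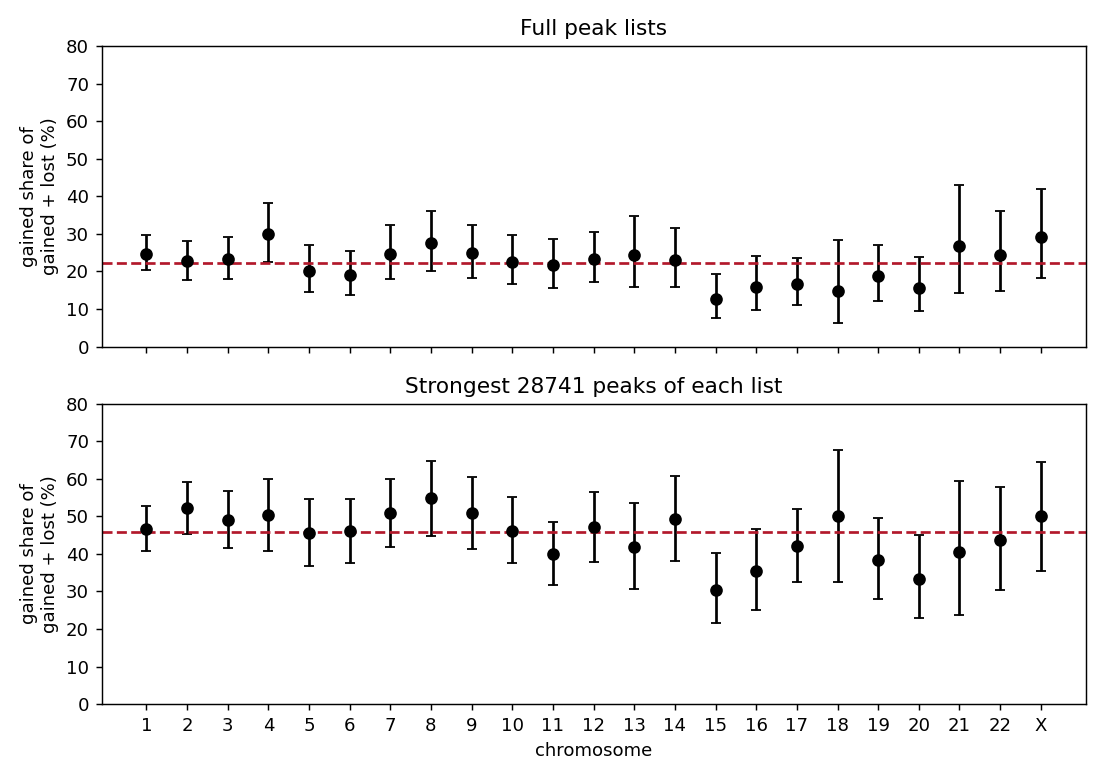
Share of gained among gained and lost regions (vertical axis, %) on each chromosome (horizontal axis), for the full lists (top) and lists of equal length (bottom). Points are shares, bars are exact 95% intervals and the dashed line is the share over all chromosomes, 22.1% and 45.8%, and chromosome 15 has the lowest share in both, 12.6% and 30.4%.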

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

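The tests on spacing, chromosomes, widths, clusters and order among shared regions were chosen after the results were seen. Fewer peaks after SAHA, higher overlap within groups, more lost than gained regions and the wider spacing of gained regions kept their direction under each alternative run, and the sizes moved. For the excess of lost regions several alternatives were weak checks. Strong calls are a subset of the same calls, and all chromosomes gave nearly the same 745 gained and 2615 lost regions. The peaks above the 50 percentile keep the relative list lengths. Without a control library, 1 list defines a lost region and 2 are still needed for a gained one. Gained and lost regions numbered 354 and 1231 among peaks above the 50 percentile of each list, 1173 and 1390 in lists of equal length, and 31 and 71 as strong calls. With 1 library left out they numbered 1363 to 3606 and 4055 to 6992, since fewer lists then define a call, and the ratio of lost to gained ran from 1.12 without SAHA replicate 2 to 5.13 without control replicate 2. SAHA libraries had 83.3 to 92.2% of the control number of peaks with 1 library left out, against 87.7% with all. Each SAHA list was shorter than each control list, so the direction of this difference is kept by construction when a library is left out. The same holds when a fixed share of each list is taken. The within-group minus between-group Jaccard index was 0.0288 without control replicate 1 to 0.0595 without SAHA replicate 1. The ratio of median distances ran from 1.96 to 6.50. The permutation p for chromosomes, 0.0848 as reported, was 0.0289 in lists of equal length and 1e-05 to 0.613 with 1 library left out, and the cause was not tested. Shared regions that moved by over 20 percentile points numbered 793, and 2290 to 2538 with 1 library left out, when fewer lists must differ. Of the 30 named regions, 28 kept their call when peaks within 200 bp were merged, whereas leaving out a library keeps each call by construction. The 2 that did not were the gained region from 173314777 on chromosome 5 and the lost region from 115479983 on chromosome 9. They lay 0.396 and 0.424 kb from the nearest shared region. A replicate block, with calls made within each replicate number and then required in both, gives the same 744 gained and 2615 lost regions by construction. The replicate numbers showed no pairing of the libraries in presence or rank, where the correlation of deviations was -0.00046 and 0.0105. Distances to shared regions did differ by number. Regions found in a single library lay farther away for replicate 1 in both groups, at 16.9 against 8.51 kb in control and 37.4 against 18.8 kb in SAHA libraries. A pairing by number is therefore not excluded. The planned promoter shares, gene lists and motif tests were not run, nor were their alternatives. The weakest peaks rested on 3 or 4 reads, so absence from a list at such levels does not show closed chromatin.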

Other observations

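Of the tests in this part, those on order among shared regions, spacing in lists of equal length, depth and shoulders of shared peaks were chosen after the results were seen. The counts of gained and lost regions in lists of equal length and among strong calls were planned, but their use as tests of list length and of weak calls was chosen after these counts were seen. Among the 21816 regions open in all 4 libraries, the order of strength also differed between the groups. Ranked by score within each library over this same set of regions, 411 regions stood over 20 percentile points higher in both SAHA libraries than in both control libraries, and 382 stood as far lower. The crossed splits gave 211 and 203 such regions in both directions together, against 793 for SAHA and control. With a gap of 10 points the counts were 1208 and 1162 against 2803, and with 30 points 30 and 20 against 179. Spearman's rho across these regions, which are not independent replicates, was 0.870 and 0.859 within groups and 0.818 to 0.825 between groups. Regions that moved up were narrower, with a median width of 219 bp, than those that moved down, with 278 bp (permutation p = 1e-05), and the width of all shared regions was 282 bp. This is the width of the merged region, which takes in the peaks of all 4 lists. Peaks within shared regions were wider in control libraries, so the width is not independent of the group in which a region ranked higher. It was not compared in the crossed splits.

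The widest move upward was on chromosome 11 from 65190258 to 65190716, from the 0.146 ± 0.011 percentile in control to the 63.7 ± 1.2 percentile in SAHA libraries (SD, n = 2 each), with 27 reads at the summit in each control library and 50.5 ± 3.5 in SAHA libraries. Score depends on the local background as well as on reads, and this region ranked near the bottom in control libraries with more reads than the shared median of 26. On chromosome X from 134063884 to 134064221 the percentile was 11.9 ± 7.4 in control and 73.5 ± 5.3 in SAHA libraries. On chromosome 2 from 13147105 to 13147275 it was 2.14 ± 2.2 and 61.7 ± 11.6. The widest move downward was on chromosome 5 from 156625647 to 156625967, from the 80.2 ± 1.6 to the 25.5 ± 2.5 percentile, with 40 ± 1.4 summit reads in control and 14.5 ± 0.71 in SAHA libraries. It was followed by chromosome 16 from 28505453 to 28505702, at the 64.4 ± 2.6 percentile in control and the 11.7 ± 4.6 in SAHA libraries. On chromosome 12 from 10711858 to 10712078 the percentile was 58.9 ± 1.5 in control and 8.90 ± 3.2 in SAHA libraries. These regions were chosen for the size of their move, so their moves are likely overstated, and over all shared regions ranking by fold in place of score gave 866 moved regions.

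The first pattern to weigh is the excess of lost over gained regions. Lists of equal length brought the ratio of lost to gained from 3.51 to 1.19, but equal lists draw these counts together whatever made the lists unequal, so this does not show a source. Lower depth is not settled by the background floors either. Both SAHA floors lay below both control floors, but the higher SAHA floor was 99.8% of the lower control floor. That gap is too small to decide with 4 libraries and an unrecorded read extension. Control replicate 1 and SAHA replicates 1 and 2 had floors of 0.250, 0.244 and 0.249 reads but 36033, 31831 and 28741 peaks. Control replicate 2 had the highest floor, 0.295 reads, but with 32995 peaks fewer than control replicate 1. The floor alone therefore did not set the list length in these libraries, although only 1 control library had a floor close to those of SAHA. Why the SAHA lists are shorter stays open, the treatment included.

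The second pattern is that gained and lost regions together exceeded the crossed pairs, although in the full lists 744 gained regions alone lay within their range. Weak calls near the threshold would give as many regions in any pairing of libraries only if the lists were alike in length. The lists were not, and the crossed patterns of the full lists held 431 to 1116 regions. Above the 50 percentile of their lists, the SAHA and control split held 3.19 times as many regions as the higher crossed split. Lost regions carried most of this, with 71 against 6 to 26 in the 4 crossed patterns. In lists of equal length, above the same percentile of the full lists, 77 lost and 43 gained regions stood against 7 to 28. These values argue against weak calls as the whole source of the lost regions, although only 2 crossed splits stand for replicate differences. In the full lists 31 gained regions were close to the highest crossed pattern. Above the 25 percentile 195 stood against 71 to 221, so for gained regions weak calls stay open. Above the 75 percentile, 4 regions against 1 and 2 are too few to tell. The treatment and an unrecorded difference in handling between the groups both remain open, since the labels give no batch.

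The third pattern is the wider spacing of gained than of lost regions from shared ones. Unequal list lengths as the whole source are argued against by a ratio of 4.86 (95% interval 3.94 to 6.05) in lists of equal length, where crossed pairs reached 1.49 (1.12 to 1.89), and a few chromosomes by the larger gained median on 23 of 23 (19 for the replicates numbered 1 against those numbered 2). Lost regions could in part be shoulders of shared peaks: without regions within 2 kb of a shared region the ratio was 2.64 (2.201 to 3.091), and that of crossed pairs reached 1.88, with overlapping intervals, so this stays open. Without control replicate 2 the ratio over all regions was 1.96, below the 2.28 of the crossed pairs with all libraries. The treatment and a difference between the groups in base composition bias, which was not tested because no hg19 sequence was used, also remain open.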
